A study of Drosophila melanogaster with 24 samples.

How the data were processed

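Polyadenylated RNA of whole adult flies was measured in 24 libraries, 3 for each combination of sex, genotype and feeding, and per the labels' protocols each vial held 15 males or 10 females that spent 24 h on food or on water before RNA was extracted. Per the labels' protocols the ΔNLS allele and the wild-type allele of the injected stock were each placed over the same deficiency. The direction of the crosses and the origin of the other chromosomes are not given in the sources used here. Groups and replicate numbers were taken from the labels, which call the number a batch.

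The tools used, per the submitters' processing notes, were bcl2fastq, FastQC 0.11.8, Picard 2.18.7, MultiQC 1.6, STAR 2.7.2a, kallisto 0.46.0 and limma, with the genome build BDGP6. What each tool was used for is not given in the sources used here. Sequencing took 2 runs, per the labels' protocols, and which library was in which run, or whether the runs divided the sexes, is not given in the sources used here. The deposited table holds counts per gene of each library, which the authors made before deposit, with the counting program, annotation release and strand setting not given in the sources used here. The deposited tables of the 8 pairwise comparisons hold log2 fold changes that the authors computed. They also hold p-values and adjusted p-values that the authors computed, and the deposited enrichment tables hold a p-value per gene category with the number of its genes as the authors counted them. The authors' model is not given in the sources used here. Of the enrichment tables only those of KEGG were compared, and the deposited tables of MSigDB categories were not used.

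The count table held 13931 genes, of which 13844 were found by identifier in the reference annotation (Ensembl release on BDGP6.54), 12781 were named by the deposited tables and 1147 by the reference alone. All 12697 genes present in both lay on the same chromosome in both, and coordinates are those of the reference. The genes roX1 and roX2 were not analysed here, and sex was checked by yolk protein genes. No pair of libraries within a group looked like a copy, with a chi-square per gene between 9.74 and 93.5 over the 24 pairs.

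Counts were tested with edgeR 4.0.16 (quasi-likelihood F test, robust, filterByExpr, TMM scaling) in R 4.3.3, in males and females apart, each with 4 groups, 12 libraries and 8 residual degrees of freedom. TMM factors lay between 0.957 and 1.04 in males and between 0.964 and 1.05 in females. There were 14 comparisons: for each sex starved against fed in each genotype, ΔNLS against WT in each feeding state and averaged over both, and the genotype by feeding interaction, and over all 24 libraries the sex by feeding interaction in WT and the sex by genotype interaction. The Benjamini-Hochberg adjusted p threshold was 0.05. Levels are CPM, counts scaled to 1e6 per library by TMM within each sex, except for the yolk protein check and the levels given for the interactions with sex, which were scaled over all 24 libraries. Where a group had no counts, a floor of 3 counts over its 3 libraries gave the smallest fold. Fixed lists of genes, 25 in all, were tested with camera of limma 3.58.1 with its preset correlation of 0.01, and again with the correlation estimated from the data. A list's members were also adjusted over the list alone. Figures and checks used Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3.

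The groups, comparisons, lists and the rule for naming genes were set before the data were examined. The rule named, per comparison, the 10 largest increases and the 10 largest decreases among genes with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the groups, which 10% of genes without a difference meet by chance with 3 against 3 libraries. It also named up to 4 members per list with the smallest adjusted p under 0.05, Lpin always, and for interactions the 10 smallest adjusted p values. The text gives a part of these genes, chosen for known function and for calls that held under omission of libraries. The levels of eca and Unc-115a, the chromosome shares and the purine and cuticle genes of the closing section were chosen after the values were seen.

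Tested on simulated counts, the fed genotype comparison in males (12718 genes) recovered 56.7% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 98.5% of those changed 4-fold, with 7 false calls among 190 (3.68%). The fed genotype comparison in females (10781 genes) recovered 31.3%, 86.6% and 93.9%, with 12 false calls among 173 (6.94%). The simulated genes varied independently of each other, without a starvation response or effects shared by the genes of a library. These rates may therefore be better than in the real libraries. Depth per library is given with the results.

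Whether the batch number pairs the libraries was checked by the correlation of deviations from the group means: libraries of the same number had a mean r of 0.0566 in males (-0.237 to 0.423, over 0.1 in 5 of 18 pairs) and -0.0376 in females (-0.388 to 0.382, over 0.1 in 7 of 18 pairs). Pairs of different number and group had a mean r of -0.0293 in males and 0.0184 in females. The best match in another group had the library's own number for 6 of 12 male and 3 of 12 female libraries. As the labels call the number a batch, a fit with it as a block is given where it changed a call. Other alternatives were RLE scaling, DESeq2 1.42.0, limma-voom, no filter or a filter of 1 CPM in 3 libraries, each library left out in turn, the 2 groups fitted alone or all 24 libraries fitted together, and for the lists the fry test and members of at least 5 CPM. For the interactions with sex and the other comparisons the libraries were also divided anew in every way, or in 100 ways where there were more.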

Results

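Polyadenylated RNA was sequenced from whole Drosophila melanogaster flies to ask which genes depend on nuclear Lipin when flies are fed or fasted. Lipin (gene Lpin) is a phosphatidate phosphatase of triglyceride synthesis that can also enter the nucleus. Flies carrying a Lipin allele without its nuclear localisation signal over a deficiency that uncovers the gene (ΔNLS) were compared with flies carrying the wild-type allele of the injected stock over the same deficiency (WT). Both genotypes thus had a single copy of Lpin. Males and females of each genotype were kept for 24 h on food (fed) or on water alone (starved). The 8 groups had 3 libraries each, 24 in all, numbered 1 to 3 by batch. Reads counted in genes ranged from 25953240 to 29543567 per male library and from 27891765 to 30413417 per female library. Between 13259 and 13357 genes had counts in a male library against 11556 to 11887 in a female one. The yolk protein gene Yp1, which is active in females, had mean levels of 1433 to 5060 CPM (counts scaled to 1e6 per library) in the female groups and at most 0.331 in the male groups. Every library fitted its labelled sex.

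Lpin (FBgn0263593, 2R:8136986-8156654, minus strand, BDGP6.54 here and below) was measured first because it is the mutated gene. A count per gene does not show whether the localisation signal is present, so its level checks nothing of the genotype label. In males its level was 140.1 ± 11.8 CPM in fed WT and 171 ± 7.9 in fed ΔNLS flies (mean ± SD, n = 3 in each group here and throughout, unless stated), a log2 difference of 0.29 ± 0.21 (SE) at adjusted p = 0.762. Starved males had 221 ± 84.3 CPM in WT and 310.3 ± 44.4 in ΔNLS. The rise with starvation passed the threshold in ΔNLS males (0.86 ± 0.21, adjusted p = 0.0174) and not in WT males (0.66 ± 0.21, adjusted p = 0.0551). The ΔNLS call was lost without fed library 2, starved library 2 or starved library 3 (adjusted p = 0.062, 0.0791 and 0.0534). In females Lpin was at 67.1 ± 6.74 CPM in fed WT, 95.4 ± 12.6 in fed ΔNLS, 79.2 ± 4.95 in starved WT and 88.4 ± 6.67 in starved ΔNLS flies. The fed females differed between genotypes (0.51 ± 0.11, adjusted p = 0.0364), but not with the batch number as a block (adjusted p = 0.0683), nor without fed WT library 1 or 2 or fed ΔNLS library 1 or 3 (adjusted p = 0.131, 0.0735, 0.0813 and 0.12). Averaged over feeding the female difference was 0.33 ± 0.08 (adjusted p = 0.0263), lost without fed WT library 1, fed ΔNLS library 3, starved WT library 3 or starved ΔNLS library 2 or 3 (adjusted p = 0.0516, 0.0514, 0.0763, 0.076 and 0.0512). Lpin did not pass between starved males (adjusted p = 0.415), between males averaged over feeding (0.207), between starved females (0.577) or with starvation in WT (0.274) or ΔNLS (0.533) females. The authors' deposited table gave adjusted p values for Lpin of 0.0435 and 0.000754 for starvation in WT and ΔNLS males, 0.0369 for starved males between genotypes and 0.0328 for fed females between genotypes.

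**Figure D1:**
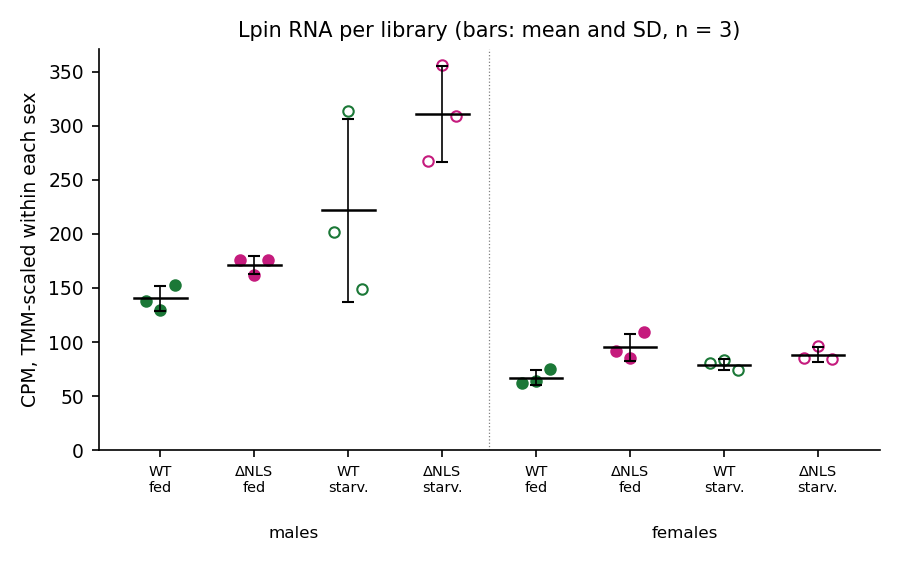
Lpin level per library, in CPM scaled within each sex, with 3 points per group and bars for the mean and SD. Starved male libraries reached group means of 221 in WT and 310.3 in ΔNLS, and the female group means lay between 67.1 and 95.4.

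WT males starved for 24 h had much less RNA of genes for digestive proteases, storage proteins and seminal fluid than fed WT males. The gut serine protease Jon25Bi (FBgn0020906, 2L:4954279-4955144) fell from 60.7 ± 6.52 to 0.785 ± 0.164 CPM, a log2 change of -6.27 ± 0.42 (SE; adjusted p = 1.23e-05). The storage protein Lsp2 (FBgn0002565, 3L:12129393-12131869) fell from 792 ± 128 to 45.0 ± 24.2 CPM (-4.14 ± 0.43), and the lipid droplet protein Lsd-1, a perilipin, from 248 ± 19.7 to 20.6 ± 8.12 CPM (-3.59 ± 0.31). AkhR, the receptor for the adipokinetic hormone that mobilises fat, fell from 81.2 ± 5.75 to 26.1 ± 4.92 CPM (-1.64 ± 0.12). Among the increases, hll, an acyl-CoA synthetase, rose from 0.623 ± 0.0637 to 32.7 ± 3.26 CPM (5.70 ± 0.13, adjusted p = 1.3e-10). Sardh, sarcosine dehydrogenase, rose from 4.47 ± 0.514 to 54.1 ± 18.5 CPM (3.60 ± 0.37) and Lst, the hormone limostatin that lowers insulin secretion, from 93.5 ± 10.1 to 267 ± 48.3 CPM (1.51 ± 0.13).

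By the lists fixed beforehand, 26 of 27 digestive serine proteases fell in starved WT males and none rose, and 27 fell when adjusted over the list alone. Of 45 seminal fluid genes 40 fell (41 adjusted over the list alone), such as Sfp24Bb (-2.08 ± 0.14) and Sfp60F (-1.76 ± 0.13). Of 25 fatty acid beta-oxidation genes 14 fell and 1 rose (15 and 1 adjusted over the list alone), among them the acyl-CoA oxidases CG9527 (-1.14 ± 0.17) and CG17544 (-0.86 ± 0.15). Of 17 lipoproteins and lipid carriers 10 fell and 2 rose, with Npc1b, which takes up sterols in the gut, at -3.96 ± 0.42 and Npc2d at -3.50 ± 0.38. Of 5 storage proteins 3 fell. Of 21 muscle genes 9 fell (14 adjusted over the list alone), including the titin-like bt (-0.51 ± 0.10). These 6 lists were lower in the camera test with its preset correlation (adjusted p = 7.09e-19, 1.29e-24, 1.73e-05, 0.00202, 0.0117 and 7.78e-06). With an estimated correlation none held (adjusted p = 0.403, 0.32, 0.516, 0.403, 0.403 and 0.403). Higher lists were spermatogenesis (3 of 26 members rose, adjusted p = 7.78e-06), ribosome biogenesis (6 of 31, such as Non1 at 0.77 ± 0.09; adjusted p = 8.31e-05) and phosphatidate and phospholipid enzymes (5 rose and 1 fell of 21, among them the phosphatidate phosphatase laza at 1.07 ± 0.17; adjusted p = 0.0243). Each of these had adjusted p = 0.403 with an estimated correlation. Oxidative phosphorylation was lower as a list although 0 of 33 members passed by edgeR (adjusted p = 0.0086, and adjusted p = 0.779 with an estimated correlation).

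Other lists in WT males went both ways. Of 22 genes of fatty acid and triglyceride synthesis 5 rose, such as the glycerol-3-phosphate acyltransferase mino (0.83 ± 0.10), and 9 fell, such as the diacylglycerol acyltransferase mdy (-0.62 ± 0.12). Of 21 lipases and lipid droplet genes 5 rose and 8 fell. Of 20 maltases, amylases and mannosidases 3 rose and 5 fell, with the maltases Mal-B1 (1.19 ± 0.22) and Mal-B2 (1.79 ± 0.37) higher. Of 25 genes of nutrient signalling 8 rose and 4 fell. Autophagy and lysosome genes had 3 higher and 2 lower of 24, detoxification genes 3 and 9 of 44, glycolysis genes 1 and 0 of 17, clock genes 0 and 1 of 9, and ovarian germline genes 1 and 1 of 25. No member passed in the lists of neurons, photoreceptors, heat shock proteins, ecdysone response or the 9 tested eggshell genes. None of these lists passed the camera test. Of 35 antimicrobial peptides and immune effectors 8 rose, such as AttA (4.37 ± 0.92), and 6 fell, such as PGRP-SC1b (-3.12 ± 0.32). The mean log2(CPM + 1) of 14 antimicrobial peptide genes was 4.28, 3.42 and 2.76 in the starved WT male libraries and between 1.78 and 1.92 in the fed ones.

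In all, edgeR called 552 genes higher and 1646 lower in starved than fed WT males, of 12718 tested, with 84 and 448 changed at least 2-fold. The total of 2198 became 1290 without fed library 1, 1264 without fed library 2 and 1402 without starved library 2, and 1269 when the 6 libraries were fitted alone.

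ΔNLS males responded to starvation with largely the same genes. Jon25Bi fell from 66.6 ± 35.0 to 1.01 ± 0.134 CPM (-6.04 ± 0.41), Lsp2 from 307 ± 106 to 19.9 ± 5.98 CPM (-3.95 ± 0.43), Lsd-1 by 3.20 on the log2 scale and AkhR by 1.42. The acyl-CoA synthetase hll rose from 0.404 ± 0.0679 to 26.5 ± 1.21 CPM (6.02 ± 0.14). The lipase-like gene CG5966 (1.87 ± 0.18) and ACC, acetyl-CoA carboxylase (0.78 ± 0.13), were among the further increases. Of the listed groups 25 of 27 proteases, 39 of 45 seminal fluid genes, 7 of 25 beta-oxidation genes and 9 of 21 muscle genes fell. The proteases had a camera adjusted p = 1.75e-20, and adjusted p = 0.342 with an estimated correlation. Of 35 immune genes 9 fell and 1 rose in ΔNLS males (list adjusted p = 0.00593, and adjusted p = 0.814 with an estimated correlation). Lipid carriers (10 of 17 lower and 2 higher), storage proteins (3 of 5 lower) and oxidative phosphorylation (4 of 33 lower) were lower as lists at adjusted p = 0.0041, 0.00185 and 0.00185. With an estimated correlation they were adjusted p = 0.442, 0.429 and 0.816. Ribosome biogenesis (7 of 31 higher), phosphatidate enzymes (6 higher and 1 lower of 21), photoreceptors (1 of 18 higher) and spermatogenesis (0 of 26 called by edgeR) were higher at adjusted p = 0.000148, 0.0165, 0.0347 and 0.0165. With an estimated correlation these were adjusted p = 0.429, 0.404, 0.816 and 0.814. The mean log2(CPM + 1) of the 14 antimicrobial peptide genes was 2.23, 3.28 and 1.8 in the fed and 2.11, 1.79 and 1.66 in the starved ΔNLS male libraries.

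The genes called in ΔNLS males numbered 737 higher and 1607 lower. Of those higher, 350 were also higher in WT males where independent lists would share 32, and of those lower 1269 were shared against 208. The log2 changes of the 2 genotypes, which share no library, correlated across genes at r = 0.845, genes not being independent replicates. The total of 2344 became 1470 without ΔNLS starved library 2 and 1354 without ΔNLS starved library 3. No gene passed the test of whether the starvation response differed between the genotypes in males (edgeR, 0 genes, with 323 at an unadjusted p under 0.05). DESeq2 called 7 and limma-voom 0, and 1 passed by edgeR without ΔNLS starved library 1. By list 7 were higher and 3 lower in this test, such as the immune list (0 of 35 called by edgeR over all genes and 9 lower adjusted over the list alone; adjusted p = 2.91e-06, and adjusted p = 0.552 with an estimated correlation). None of the 10 held with an estimated correlation (adjusted p = 0.552 to 0.873), and with the batch number as a block fatty acid synthesis and ovarian germline were lost (adjusted p = 0.0517 and 0.05).

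**Figure D2:**
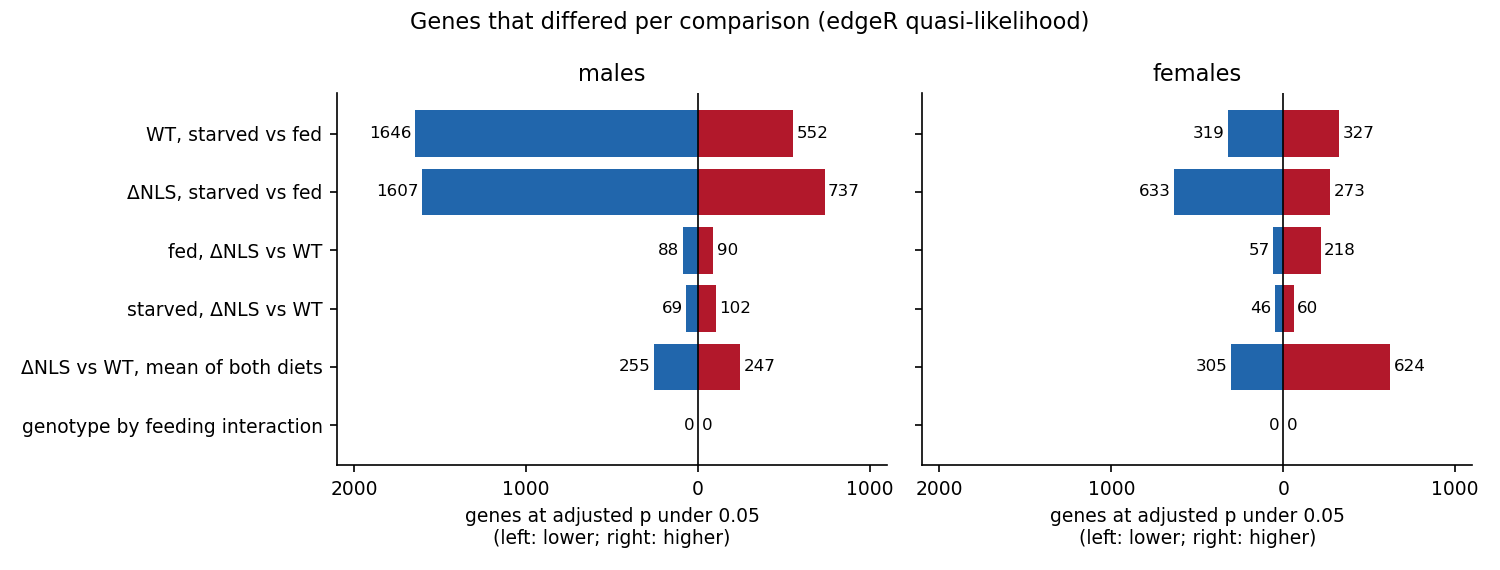
Genes higher (right) and lower (left) at adjusted p under 0.05 in each comparison within males and within females. Starvation changed 2198 genes in WT males and 646 in WT females, and the genotype, averaged over feeding, 502 and 929.

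WT females starved for 24 h had more RNA of many carbohydrate-digesting enzymes and some lipases than fed WT females, and less of many eggshell, yolk and digestive protease genes. Amyrel (FBgn0020506, 2R:16651095-16652699), an amylase-related gene, rose from 0.116 ± 0.171 to 23.7 ± 11.7 CPM (log2 7.61 ± 0.71, adjusted p = 0.000127). The gene tobi (FBgn0261575, 3R:25344761-25346921), an alpha-glucosidase known as a target of brain insulin, rose from 2.46 ± 0.145 to 43.5 ± 3.16 CPM (4.14 ± 0.66). The lipase-like gene CG5966 rose from 48.7 ± 5.76 to 342 ± 12.7 CPM (2.81 ± 0.12, adjusted p = 3.5e-07) and bmm, the adipose triglyceride lipase brummer, from 95.2 ± 3.41 to 155.8 ± 8.38 CPM (0.71 ± 0.08). The cuticle gene TwdlN, at 0 in all fed WT females, reached 10.04 ± 9.39 CPM, at least 286-fold higher against a floor of 3 counts over the group. Decreases included fit, a fat-body peptide of satiety, from 29.4 ± 12.9 to 0.576 ± 0.452 CPM (-5.69 ± 0.58). The yolk protein gene Yp2 fell from 3071 ± 1055 to 765 ± 257 CPM (adjusted p = 0.00259) and exu, which localises RNA in the oocyte, from 325 ± 22.3 to 149.6 ± 17.2 CPM (-1.12 ± 0.10).

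Of 19 maltases, amylases and mannosidases tested in females 11 rose and none fell (13 adjusted over the list alone), with a median log2 change of 1.74. Of 17 lipases and lipid droplet genes 7 rose, such as CG6283 (3.25 ± 0.32) and CG6277 (3.01 ± 0.35), and 3 fell, such as CG17192 (-4.30 ± 0.67). Of 28 digestive serine proteases 15 fell and 1 rose (20 and 1 adjusted over the list alone), with Jon65Ai at -3.69 ± 0.28. Of 26 eggshell and yolk genes 12 fell (21 adjusted over the list alone), with the vitelline membrane gene psd at -3.23 ± 0.57. The camera adjusted p values of these 4 lists were 6.87e-13, 0.000341, 8.53e-16 and 3.31e-16, and each had adjusted p = 0.29 with an estimated correlation. Smaller numbers rose among genes of detoxification (9 of 43, such as Cyp6w1 at 1.15 ± 0.19 and Ugt86Dd at 1.42 ± 0.21), glycolysis and gluconeogenesis (5 of 17, such as Pepck1 at 1.38 ± 0.25 and Pgi at 0.60 ± 0.09), fatty acid and triglyceride synthesis (5 of 22, such as ACC at 0.76 ± 0.13) and beta-oxidation (3 rose and 1 fell of 25). These had camera adjusted p = 1.51e-05, 0.000265, 0.014 and 0.00962, and adjusted p = 0.551 with an estimated correlation in each case. The neuron list was higher with no member called by edgeR (0 of 19; adjusted p = 0.00327, and adjusted p = 0.629 with an estimated correlation), and the ecdysone response lower with 2 of 20 (adjusted p = 0.014, and adjusted p = 0.551 with an estimated correlation). Of 3 storage proteins 1 fell (list adjusted p = 0.0377, and adjusted p = 0.447 with an estimated correlation). Of 27 ovarian germline genes 3 fell, and of 33 immune genes 3 fell.

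These calls amounted to 327 genes higher and 319 lower of 10781 tested. The total of 646 became 373 without fed WT library 2, 314 without starved WT library 2 and 338 when the 6 libraries were fitted alone, and DESeq2 called 1019. Fed WT library 1 lay apart from the other female libraries on the second principal component and had the lowest mitochondrial share of counts, 3.16%, and its omission left the total within 1.5 times.

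**Figure D3:**
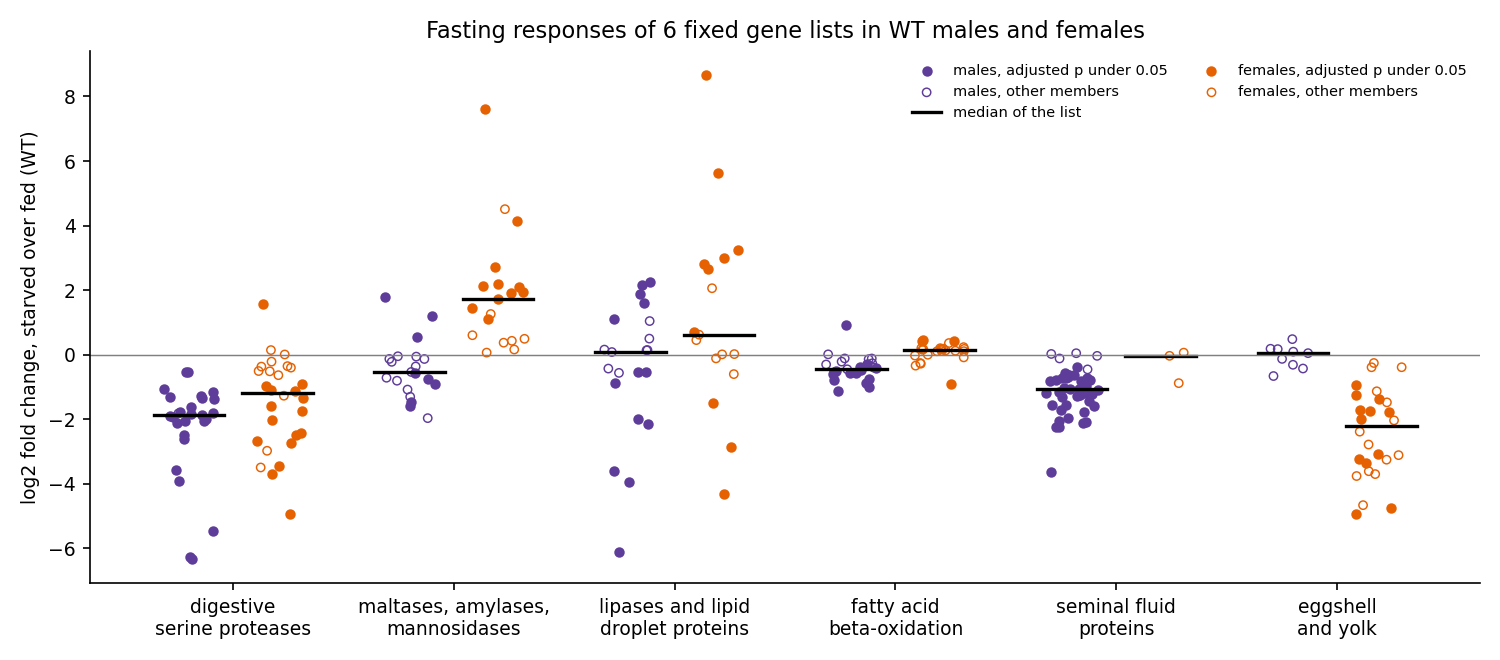
Log2 fold change, starved over fed, of each member of 6 fixed gene lists in WT males and WT females, with filled points for adjusted p under 0.05 and a bar at the list's median. Digestive proteases lay mostly below 0 in both sexes (26 of 27 fell in males, 15 of 28 in females), while carbohydrate-digesting enzymes had a median of 1.74 in females and -0.549 in males.

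With starvation ΔNLS females, too, had less RNA of many eggshell, yolk and digestive protease genes. Some genes of oxidative phosphorylation were also called lower, though by edgeR no gene passed the test of a response that differed from WT. The vitelline membrane gene Vm26Aa fell from 693 ± 70.5 to 13.4 ± 14.3 CPM (-5.69 ± 1.07), Yp1 from 5160 ± 237 to 1496 ± 300 CPM (-1.79 ± 0.21). The protease Jon66Ci fell from 16.2 ± 6.64 to 0.476 ± 0.259 CPM (-5.08 ± 0.56) and COX8, a cytochrome oxidase subunit, from 187 ± 18.5 to 101 ± 5.44 CPM (-0.88 ± 0.15). Amyrel rose from 0.121 ± 0.11 to 7.33 ± 1.59 CPM (5.88 ± 0.72), CG5966 by 2.03 ± 0.11 and bmm by 0.61 ± 0.08. Of 26 eggshell and yolk genes 17 fell, of 28 proteases 21, of 33 oxidative phosphorylation genes 14 (27 adjusted over the list alone), of 20 ecdysone response genes 9, including the steroidogenic genes spo and phm, and of 21 muscle genes 4. In turn 6 of 19 maltases and amylases and 7 of 43 detoxification genes rose. The adjusted p values of these 7 lists were 1.26e-15, 6.29e-19, 1.59e-11, 7.75e-06, 3.26e-05, 1.01e-05 and 8.25e-06. With an estimated correlation they were adjusted p = 0.323, 0.323, 0.451, 0.323, 0.669, 0.585 and 0.653. Lipases (7 higher and 3 lower of 17) were also higher and storage proteins (2 of 3 lower) lower, at adjusted p = 0.0168 and 0.039, and adjusted p = 0.562 and 0.451 with an estimated correlation.

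In ΔNLS females 273 genes were higher and 633 lower. Of these, 178 and 218 were shared with WT females, where independent lists would share 8.28 and 18.7, with r = 0.801 across genes. Every omission of a single library moved the total of 906, to 565, 578 and 555 without ΔNLS fed libraries 1, 2 and 3 and to 379, 451 and 519 without ΔNLS starved libraries 1, 2 and 3, and DESeq2 called 1789. The test of a different starvation response between genotypes called 0 genes in females by edgeR, with 934 at an unadjusted p under 0.05, 0 by limma-voom and 20 by DESeq2. By list, oxidative phosphorylation was lower in this test (median log2 -0.408, adjusted p = 1.31e-12, and adjusted p = 0.576 with an estimated correlation), with 0 of 33 members called by edgeR over all genes and 7 lower adjusted over the list alone. Between genotypes this list was higher in fed ΔNLS females (median log2 0.176) and lower in starved ones (-0.222), with adjusted p = 0.721 and 0.924 with an estimated correlation. In all 8 lists were lower in this test and none higher, among them muscle and glycolysis (adjusted p = 2.03e-06 and 1.03e-05, and adjusted p = 0.576 with an estimated correlation). None of the 8 held (adjusted p = 0.576 to 0.647 with an estimated correlation).

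Fed males of the 2 genotypes differed in few genes, some of them very strongly. The alpha-glucosidase tobi was at 49.7 ± 5.38 CPM in WT and 370.0 ± 15.5 in ΔNLS males (log2 2.90 ± 0.14, adjusted p = 2.17e-07). HSPBAP1 (FBgn0263025, 3R:27695235-27696531) was at 188 ± 27.7 and 4.01 ± 0.901 CPM (-5.55 ± 0.21, adjusted p = 5.22e-08). CG17177 (FBgn0036440, 3L:14697313-14701678) was at 56.7 ± 3.47 and 3.19 ± 0.754 CPM (-4.15 ± 0.17) and Culd (FBgn0035880, 3L:8352355-8356296) at 156.5 ± 8.22 and 45.4 ± 7.46 CPM (-1.78 ± 0.15). CG13675 was at 0.132 ± 0.0211 in WT and 13.3 ± 2.78 CPM in ΔNLS males (6.61 ± 0.26). The p24-family gene p24-2 (FBgn0053105, 3R:9687402-9692794) was at 0 in fed WT males and 11.7 ± 2.88 CPM in ΔNLS males, at least 326-fold higher. Unc-115b (FBgn0260463, 3R:9687060-9692775) was at 0.312 ± 0.275 and 35.3 ± 15.8 CPM (6.80 ± 0.74). These last 2 genes overlap on the same strand and lie between related genes, eca and Unc-115a, so that how reads were divided among them is uncertain. In fed males the means were 65.5 and 67.3 CPM for eca in WT and ΔNLS and 154.9 and 183 for Unc-115a. The mean of Unc-115a was also higher in ΔNLS in starved males (155 and 190.5 CPM), fed females (68.7 and 104.4 CPM) and starved females (75.1 and 88.9 CPM). Starved ΔNLS female library 2 had 0 counts of both p24-2 and Unc-115b, while each of the other 11 ΔNLS libraries had at least 232 of p24-2 and 255 of Unc-115b. Its levels of tobi (279 CPM) and Culd (30.2 CPM) lay with those of the other starved ΔNLS females. The genes p24-2 and Unc-115b thus did not follow the genotype label in every library.

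By list, 4 of 44 detoxification genes were lower in fed ΔNLS males, among them GstD3 (-0.83 ± 0.10), Cyp6a20 (-1.39 ± 0.10) and Cyp6a9 (-0.81 ± 0.12), with list adjusted p = 0.000547 and adjusted p = 0.924 with an estimated correlation. Of 16 heat shock genes 2 were higher (adjusted p = 0.00521, and adjusted p = 0.783 with an estimated correlation), and 1 of 45 seminal fluid genes was higher (adjusted p = 0.000285, and adjusted p = 0.924 with an estimated correlation). No member of the photoreceptor list passed by edgeR over all genes (0 of 18, with 5 lower adjusted over the list alone), though the list was lower (adjusted p = 3.33e-08, and adjusted p = 0.866 with an estimated correlation). The neuron list was lower too (0 of 19 called by edgeR; median log2 -0.104, adjusted p = 0.00726, and adjusted p = 0.924 with an estimated correlation). Lipases (3 of 21 higher), digestive proteases (1 higher, 2 lower of 27), fatty acid synthesis (0 of 22) and phosphatidate enzymes (0 of 21) did not pass as lists. The genes called numbered 90 higher and 88 lower in fed ΔNLS than fed WT males. The total of 178 became 94 without WT library 1, 97 without ΔNLS library 1, 73 without WT library 2 and 90 without ΔNLS library 2, and DESeq2 called 338.

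Starved males differed between the genotypes in much the same genes. The level of tobi was 72.1 ± 12.2 CPM in WT and 514 ± 66.9 in ΔNLS (2.83 ± 0.14), HSPBAP1 88.3 ± 20.3 and 4.03 ± 0.0526 (-4.45 ± 0.21) and Culd 126 ± 20.7 and 47.4 ± 6.74 CPM (-1.41 ± 0.15). The lipase-like gene CG6295 was at 5.72 ± 2.99 and 28.6 ± 6.31 CPM (2.33 ± 0.34), and daw, an activin ligand, at 38.9 ± 4.51 and 20.3 ± 1.3 CPM (-0.94 ± 0.10). Of 21 lipases and lipid droplet genes 4 were higher and none lower (list adjusted p = 0.0119, and adjusted p = 0.812 with an estimated correlation). The antimicrobial peptide and immune list was lower (median log2 -0.553, adjusted p = 1.98e-06, and adjusted p = 0.812 with an estimated correlation), with 1 of 35 members higher over all genes, and 1 higher and 10 lower adjusted over the list alone. Fatty acid and triglyceride synthesis, beta-oxidation and glycolysis were higher as lists with no member called by edgeR over all genes (0 of 22, 0 of 25 and 0 of 17), and so were seminal fluid (2 of 45 higher) and heat shock genes (2 of 16 higher). Their adjusted p values were 0.0417, 0.0417, 0.044, 0.00599 and 0.0417, and adjusted p = 0.812 with an estimated correlation. Storage proteins, photoreceptors and spermatogenesis were lower with no member called by edgeR over all genes (0 of 5, 0 of 18 and 0 of 26), at adjusted p = 0.0119, 0.0417 and 0.0417, and adjusted p = 0.812 with an estimated correlation. Peptide levels stood apart in WT starved libraries 1, 2 and 3 (4.28, 3.42 and 2.76 on the log2 scale given above, against 2.11, 1.79 and 1.66 in ΔNLS). The starved libraries also differed in the size of their starvation response. Over 1619 genes called in the same direction with starvation in both genotypes, the mean log2 change towards the starved state was 0.839, 1.22 and 0.702 in WT libraries 1, 2 and 3 and 0.82, 1.04 and 0.981 in ΔNLS libraries 1, 2 and 3.

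The starved comparison called 102 genes higher and 69 lower, of which 66 and 45 were also called in fed males (0.722 and 0.477 for independent lists; r = 0.699 across genes, no library shared). The total of 171 became 107, 267 and 101 without WT libraries 1, 2 and 3, 99 without ΔNLS library 2 and 85 without ΔNLS library 3, 73 when the 6 libraries were fitted alone and 346 by DESeq2. Averaged over feeding, 247 genes were higher and 255 lower in ΔNLS males (6 libraries of each genotype). Among these, mthl8, a methuselah-like receptor, was higher by 1.23 ± 0.09, the cohesin gene SA-2 by 1.77 ± 0.13, the fatty acid synthase FASN2 by 0.80 ± 0.15, Lip3 by 2.14 ± 0.27 and the antibacterial CecA1 by 1.15 ± 0.13. The proteases gammaTry and yip7 were lower (-2.64 ± 0.42 and -0.44 ± 0.08) while Jon99Fii was higher (2.83 ± 0.41). Of 16 heat shock genes 3 were higher (DnaJ-1 0.41 ± 0.05, Hsp27 0.40 ± 0.06, Hsp70Bb 0.64 ± 0.11) and of 44 detoxification genes 2 higher and 5 lower. These 2 lists had adjusted p = 0.0101 and 0.0176, and adjusted p = 0.778 with an estimated correlation. Lipases (4 higher and 2 lower of 21), seminal fluid (3 of 45 higher), glycolysis (0 of 17 called by edgeR) and ribosome biogenesis (0 of 31 called by edgeR) were higher at adjusted p = 0.0395, 0.000121, 0.0277 and 0.0437. Photoreceptors (1 of 18 lower), storage proteins (2 of 5 lower) and the immune list (1 of 35 higher) were lower at adjusted p = 2.12e-05, 0.0182 and 0.00125. All 7 had adjusted p = 0.778 with an estimated correlation. DESeq2 called 762 genes.

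**Figure D4:**
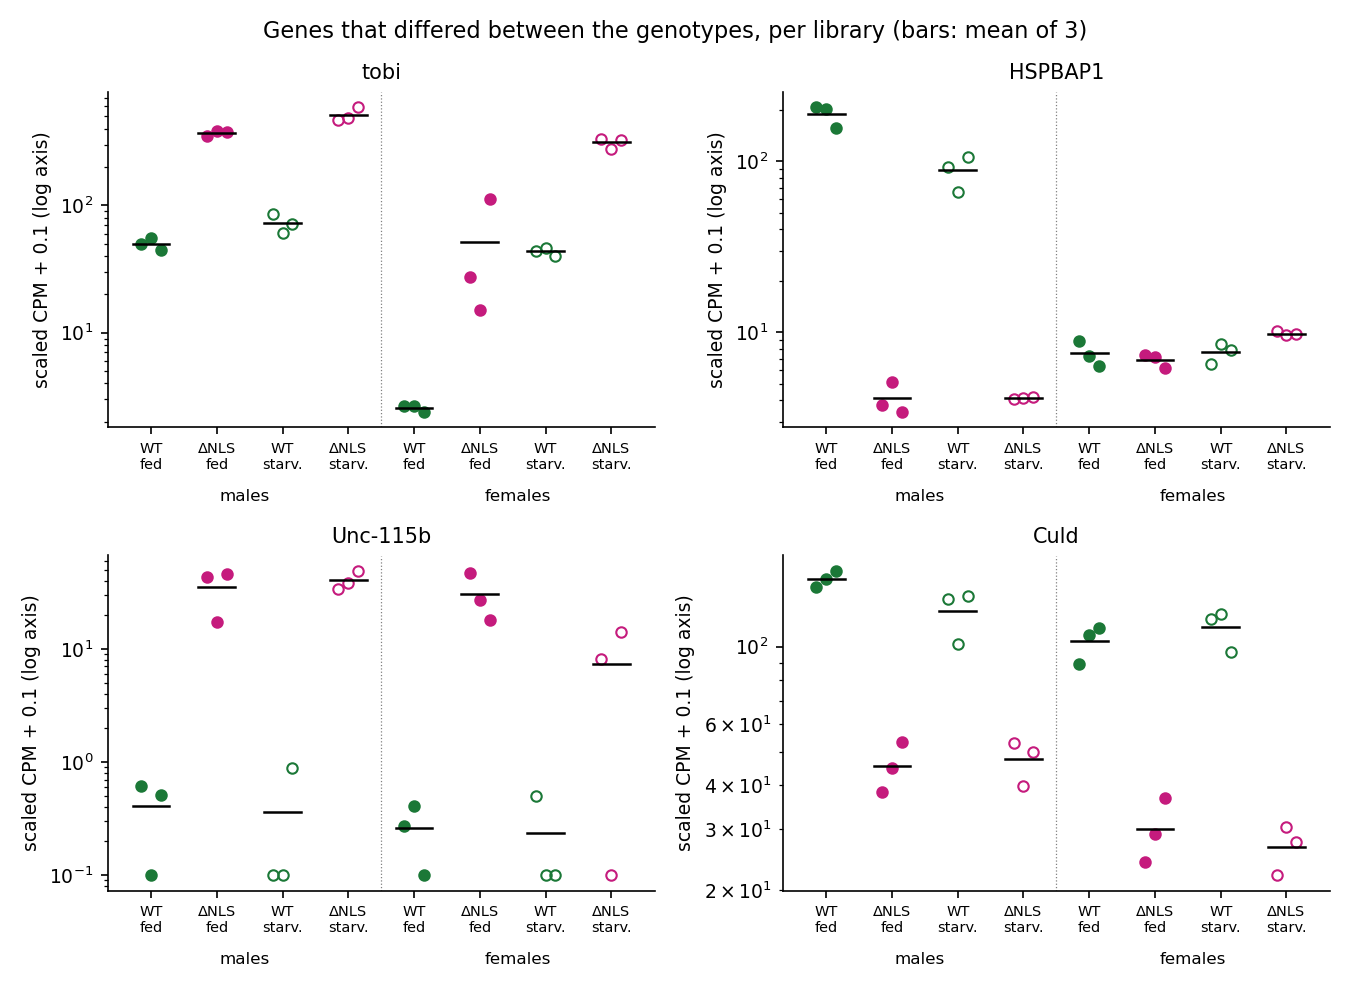
Levels of tobi, HSPBAP1, Unc-115b and Culd in each of the 24 libraries, in CPM scaled within each sex plus 0.1 on a log axis, with bars at the mean of 3. In fed males tobi was at 49.7 in WT and 370.0 in ΔNLS, HSPBAP1 differed between genotypes in males (188 and 4.01) and Culd was lower in ΔNLS flies of both sexes.

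Fed females of the 2 genotypes differed in other genes besides. Jon99Fii (FBgn0039777, 3R:30487016-30487928), a serine protease gene, was at 20.1 ± 4.09 CPM in WT and 211 ± 104 in ΔNLS females (log2 3.39 ± 0.36, adjusted p = 0.000984). CG18278 (FBgn0033836, 2R:13408042-13409887) was at 1.4 ± 0.145 and 9.98 ± 0.994 CPM (2.83 ± 0.17), mthl8 at 2.2 ± 1.34 and 15.2 ± 0.949 (2.79 ± 0.37). The adhesion molecule gene Dscam4 was at 11.3 ± 1.49 and 39.7 ± 3.97 (1.82 ± 0.14) and the lipid carrier Npc2f at 8.93 ± 1.19 and 26.9 ± 5.55 CPM (1.59 ± 0.21). Culd was lower, at 103.7 ± 12.7 and 29.9 ± 6.37 CPM (-1.79 ± 0.17), as were CG14406 (-3.08 ± 0.34), the heat shock gene Hsp70Bb (18.7 ± 7.49 and 3.81 ± 0.2 CPM, -2.29 ± 0.27) and the spindle checkpoint kinase BubR1 (-1.40 ± 0.18). The mean of tobi was 2.46 ± 0.145 in WT and 51.4 ± 52.6 CPM in ΔNLS females (4.38 ± 0.66, adjusted p = 0.00901), a call lost without WT library 1 (adjusted p = 0.0924).

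The muscle list was higher in fed ΔNLS females, with 2 of 21 members called over all genes and 21 adjusted over the list alone, at a median log2 of 0.562 (adjusted p = 2.87e-08, and adjusted p = 0.721 with an estimated correlation). Of 28 digestive proteases 5 were higher, such as Jon65Aii (1.37 ± 0.21), and of 18 lipid carriers 3. The ovarian germline list was lower with 0 of 27 called by edgeR over all genes, and 1 higher and 7 lower adjusted over the list alone. These 3 lists had adjusted p = 0.00442, 0.0175 and 0.00345, and adjusted p = 0.721 with an estimated correlation. Fatty acid and triglyceride synthesis (0 of 22 called by edgeR over all genes, and 8 higher and 1 lower adjusted over the list alone), oxidative phosphorylation (0 of 33 called by edgeR; median log2 0.176), neurons (0 of 19 called by edgeR) and nutrient signalling (1 of 24 higher) were higher too. These had adjusted p = 0.0105, 0.00345, 0.00345 and 0.0273, and adjusted p = 0.721 with an estimated correlation. The mitochondrial share of counts separated the genotypes in females, at 3.16 to 4.86% in the 6 WT and 5.02 to 6.33% in the 6 ΔNLS libraries, fed and starved together. The antimicrobial peptide list was higher with 0 of 33 called by edgeR, over all genes or adjusted over the list alone (adjusted p = 0.00442, and adjusted p = 0.721 with an estimated correlation). Its mean log2(CPM + 1) over 14 peptide genes was 3.48, 1.83 and 1.5 in ΔNLS libraries 1, 2 and 3 against 1.21, 1.37 and 1.68 in WT. Fed females had 218 genes higher and 57 lower in ΔNLS than in WT, and 81 and 24 with the batch number as a block. The total of 275 became 79 and 133 without WT libraries 1 and 2, 111, 158 and 86 without ΔNLS libraries 1, 2 and 3, 47 when the 6 libraries were fitted alone, 1821 by DESeq2 and 2269 when all 24 libraries were fitted together. WT library 1, whose omission left 79, lay apart on the second principal component (44.5, against 10.6 and 13.7 in WT libraries 2 and 3). The lists were not refitted without single libraries, so how far they rest on it is not known.

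Starved females kept several of these differences. CG18278 was at 1.09 ± 0.172 CPM in WT and 10.3 ± 1.51 in ΔNLS (3.23 ± 0.18), Culd at 113 ± 14.6 and 26.5 ± 4.19 (-2.10 ± 0.17) and CG14406 at 19.8 ± 1.87 and 3.38 ± 1.91 CPM (-2.55 ± 0.31). The yolk protein gene Yp3 was at 3331 ± 883 and 1127 ± 54.7 CPM (-1.56 ± 0.22). The mean of tobi was 43.5 ± 3.16 and 313.5 ± 29.6 CPM (2.85 ± 0.57, adjusted p = 0.0467), a call lost with the batch number as a block (adjusted p = 0.0916) and without any 1 of the 6 libraries (adjusted p = 0.0842 to 0.235), although the 3 ΔNLS values (333, 279 and 328) lay above the 3 WT values (44.1, 46.4 and 40.1). Oxidative phosphorylation was lower as a list in starved ΔNLS females, with 0 of 33 members called by edgeR over all genes and 12 lower adjusted over the list alone (median log2 -0.222, adjusted p = 1.22e-06). So was glycolysis, with 0 of 17 called by edgeR over all genes and 7 lower adjusted over the list alone (adjusted p = 0.000506). Both had adjusted p = 0.924 with an estimated correlation. Of 43 detoxification genes 2 were higher (adjusted p = 0.00658, and adjusted p = 0.924 with an estimated correlation). Eggshell and yolk genes (1 of 26 lower), ovarian germline (0 of 27), ribosome biogenesis (0 of 31) and ecdysone response (0 of 20 called by edgeR) were lower at adjusted p = 0.0228, 0.0147, 0.00658 and 0.026, and adjusted p = 0.924 with an estimated correlation. The immune list (1 of 33 higher) passed at adjusted p = 0.0497, and not with the batch number as a block (adjusted p = 0.0555) or with an estimated correlation (adjusted p = 0.924).

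The starved females had 60 genes higher and 46 lower in ΔNLS, and 25 and 21 with the batch number as a block. The total of 106 became 43 and 38 without WT libraries 1 and 3, 65, 45 and 36 without ΔNLS libraries 1, 2 and 3, 462 by DESeq2 and 266 when all 24 libraries were fitted together. With the fed comparison it shared 43 genes higher and 20 lower, where independent lists would share 1.21 and 0.243 (r = 0.557 across genes, no library shared). Averaged over feeding, 624 genes were higher and 305 lower in ΔNLS females (384 and 147 with the block). Of these, tobi (3.62 ± 0.43), GLaz, a lipocalin (0.38 ± 0.05) and the lipase-like CG6295 (1.69 ± 0.23) were higher, and Hsp70Bbb (-2.43 ± 0.30), Hsp70Bc (-1.29 ± 0.22) and the clock gene per (-0.50 ± 0.09) lower. Of 21 muscle genes 8 were higher (15 adjusted over the list alone), of 43 detoxification genes 10 higher and 2 lower, of 33 immune genes 3 higher and 1 lower and of 27 ovarian germline genes 4 lower. The adjusted p values of these lists were 2.56e-06, 0.0255, 0.00316 and 0.00154, and all had adjusted p = 0.849 with an estimated correlation. Lipid carriers (4 of 18) were higher and ribosome biogenesis genes (2 of 31) lower, each at adjusted p = 0.0433, and adjusted p = 0.849 with an estimated correlation. The peptide genes stood at 3.84 on the log2 scale in starved ΔNLS library 2 against 1.39 and 1.83 in libraries 1 and 3. The averaged total of 929 became 550 and 1410 without fed WT libraries 1 and 2, 485 and 477 without fed ΔNLS libraries 1 and 3, 358 without starved WT library 3, 365 and 392 without starved ΔNLS libraries 2 and 3, and 2055 by DESeq2.

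The response of WT flies to starvation differed between the sexes in 679 genes, 382 with a higher and 297 with a lower log2 change in females (edgeR interaction test over all 24 libraries, 13012 genes). Jabba, a lipid droplet protein, went from 164 to 23.7 CPM in males (-2.92) and from 814 to 710 in females (-0.21, adjusted p = 0.511). Amyrel changed by 7.61 in females and -0.71 in males, a difference of 8.22 ± 0.89 (SE), and exu by -1.12 in females and 0.18 in males, a difference of -1.43 ± 0.14. Of 20 maltases, amylases and mannosidases 10 had a higher change in females (16 higher and 1 lower adjusted over the list alone; adjusted p = 1.22e-14, and adjusted p = 0.101 with an estimated correlation). The lipase list (6 higher and 1 lower of 21) was higher in females at adjusted p = 8.88e-09, and held with adjusted p = 0.00778 with an estimated correlation. The seminal fluid list also passed (adjusted p = 1.33e-19, and adjusted p = 0.0108 with an estimated correlation), but only 3 of its 45 genes had enough counts to be tested in females, so that this result restates the fall in males and gives no female response. Beta-oxidation genes were higher (9 higher and 1 lower of 25) and ribosome biogenesis genes lower (9 of 31), at adjusted p = 6.65e-10 and 7.29e-08, and adjusted p = 0.163 and 0.199 with an estimated correlation. In all 14 lists were higher and 6 lower in females. Only the lipase and seminal fluid lists held with an estimated correlation, and autophagy was lost with the batch number as a block (adjusted p = 0.0577). Among the lower lists, eggshell and yolk had only 9 of 26 members tested in males and spermatogenesis 7 of 26 in females, so these mostly describe 1 sex. The 679 can also include genes near the floor in 1 sex, such as CG15337, at 0.0558 CPM in fed and 1.81 in starved WT females. Between the sexes, 90 genes were higher in both and 150 lower in both in starved WT flies (11.6 and 41.1 for independent lists), and 18 went opposite ways, with r = 0.312 over the 10508 genes tested in both. The median log2 interaction of all genes was -0.115. The total of 679 became 377, 345, 313 and 1092 without male fed libraries 1 and 2 and male starved libraries 2 and 3, 412 without female fed library 1 and 447 and 329 without female starved libraries 1 and 2, and 1068 by DESeq2.

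The genotype difference, averaged over feeding, differed between the sexes in 770 genes, 415 with a higher and 355 with a lower log2 difference in females. HSPBAP1 was at 142 CPM in WT and 4.2 in ΔNLS males (-5.00) and at 7.16 and 7.92 in females (0.12). CG13032 was at 2.5 and 0.049 CPM in WT and ΔNLS females (-5.56) and at 117.7 and 124.7 in males (0.09). Hsp70Bb was lower in ΔNLS females (-2.01) and higher in ΔNLS males (0.64), an interaction of -2.65 ± 0.22. Hsp70Bb (3R:12505793-12508139) and Hsp70Bbb (3R:12502510-12504856) lie side by side, and how reads were divided between them was not examined. In females 3 of 16 heat shock genes were lower and 0 higher averaged over feeding, while the median log2 of the list was 0.121. The immune list (4 of 35 higher), the muscle list (7 of 21) and the detoxification list (7 of 44) had a higher difference in females, at adjusted p = 3.97e-06, 1.37e-06 and 0.000541, and adjusted p = 0.704 with an estimated correlation. In all 6 lists were higher and 4 lower, and none held (adjusted p = 0.704 to 0.73 with an estimated correlation). The seminal fluid list, among the lower ones, again had only 3 of 45 members tested in females. Of the genes called in each sex, 77 were higher in both and 27 lower in both (11.3 and 5.71 for independent lists), and 9 went opposite ways. The total of 770 fell to between 264 and 411 without any 1 of 12 libraries (male WT fed 1 and 2, male WT starved 3, male ΔNLS fed 1 and 3, male ΔNLS starved 1 and 3, female WT fed 1, female WT starved 3, female ΔNLS fed 3, and female ΔNLS starved 2 and 3). It became 1498 and 1184 without female WT fed libraries 2 and 3, 1207 without female WT starved library 2 and 1570 by DESeq2.

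The genotype calls were spread unevenly over the chromosomes. In males 317 of 502 genes (63.1%) lay on chromosome 3, which held 43.7% of the genes tested (Fisher's exact test, two-sided, p = 4.77e-19). On the X lay 18 (3.59%), and it held 15.7% of the genes tested (Fisher's exact test, p = 1.17e-18). In females 439 of 929 (47.3%) lay on chromosome 3, with 44% tested (Fisher's exact test, p = 0.0381). On the X lay 177 (19.1%), with 16.2% tested (Fisher's exact test, p = 0.0175). The X-linked share differed between the sexes (Fisher's exact test, p = 1.18e-18). Genes within 2 Mb of Lpin made up 3.78% of the male calls and 4.18% of the genes tested (Fisher's exact test, p = 0.733). Of the genes called with starvation in WT males 44.2% lay on chromosome 3 (Fisher's exact test, p = 0.636) and 13.3% on the X, below the 15.7% tested (Fisher's exact test, p = 0.000635).

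**Figure D5:**
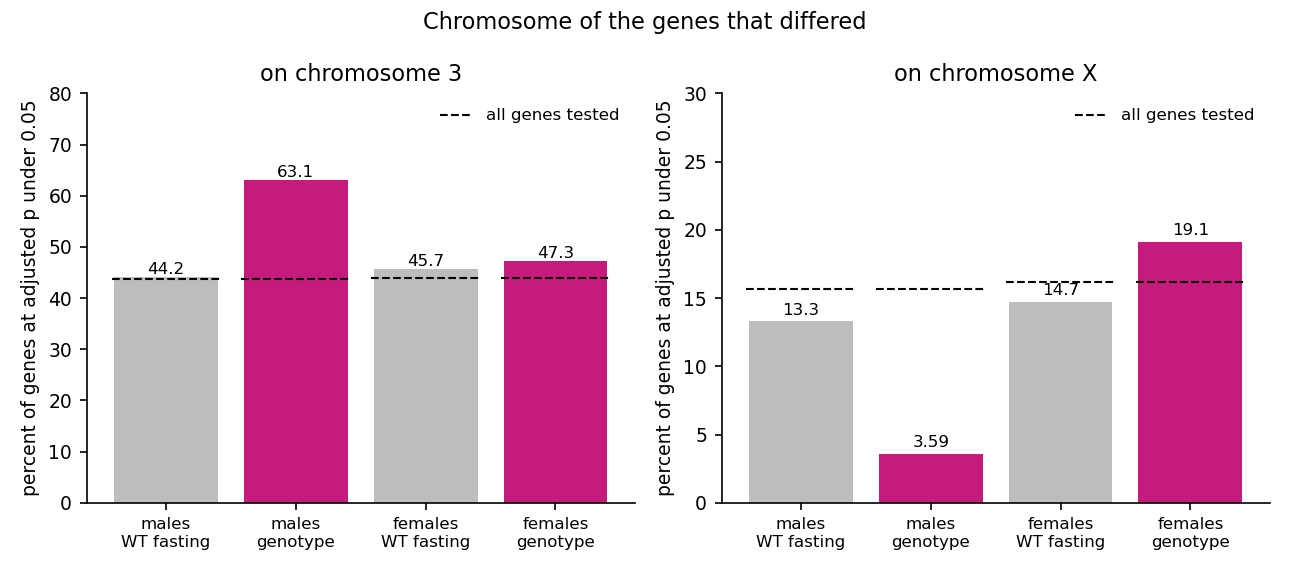
Percent of called genes on chromosome 3 (left) and on the X (right) for starvation in WT flies (grey) and for genotype averaged over feeding (magenta), with a dashed line for all genes tested. Of the male genotype calls 63.1% were on chromosome 3 and 3.59% on the X.

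The authors' deposited tables of the 8 pairwise comparisons gave adjusted p under 0.05 for 2309 and 3352 genes with starvation in WT and ΔNLS males, 790 and 2779 in WT and ΔNLS females. Genotype comparisons of the authors' deposited tables had 415 and 269 such genes between fed and between starved males of the 2 genotypes, and 366 and 344 between females. Their log2 fold changes, from the authors' deposited tables, correlated with those of edgeR across genes at r = 0.9008 (fed females) to 0.9828 (ΔNLS males). Of the genes called by edgeR, the authors' deposited tables called 2001 of 2195 in WT male starvation and 102 of 103 between starved females, all in the same direction. Among KEGG categories, the only ones compared here, the authors' deposited tables put biosynthesis of unsaturated fatty acids first for WT male starvation (adjusted p = 9.95e-09), galactose metabolism for WT female starvation (adjusted p = 1.34e-08), lysosome for fed males between genotypes (adjusted p = 0.0114) and carbon metabolism for starved females between genotypes (adjusted p = 1.24e-07).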

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

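Of the tests in this part, those of chromosome 3, of a common X and of ovarian RNA were chosen only after the result they concern was seen, as was the comparison of a split of starved males with the size of the starvation response.

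A tested difference between the sexes flagged 2 counts and 20 genes. The response to starvation in WT flies differed between the sexes in 679 genes. The 10 genes with the smallest adjusted p, with the log2 change in females minus that in males, were CG1979 (2.50), CG3739 (3.844), CG4734 (2.715), exu (-1.431), the lipid droplet gene Jabba (2.599), CG11131 (4.778), Amyrel (8.215), the lysozyme gene LysE (-3.485), CG4741 (1.78) and CG15337 (4.458). The difference between genotypes differed between the sexes in 770 genes, with HSPBAP1 (5.12), CG13032 (-5.637), CG8565 (-5.719), CG8100 (6.63), CG32572 (-2.723), Hsp70Bb (-2.652), CG4970 (-5.276), Dhc98D (1.783), CG9981 (2.872) and Dscam4 (1.263) first. CG8100 was not tested in females alone because its counts there were too low. The 10 genes of sex by feeding kept an adjusted p under 0.05 without any 1 of the 12 WT libraries (the ΔNLS libraries were not left out there), and those of sex by genotype without any 1 of the 24.

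The genes that differ at least 4-fold between the genotypes, 77 in either sex, could come from the Lipin allele or from other background of the stocks. Of these, 1.3% lay within 2 Mb of Lpin against 4.1% of the genes tested, which argues against a stretch of other background beside the mutated gene. A share of 74% had a mean of at least 1 CPM in 1 genotype, which argues against low depth. On chromosome 3 lay 55.8% against 43.6% of those tested (Fisher's exact test, p = 0.0374), while 50.6% of the genes changed at least 4-fold by starvation in WT flies lay there too. In males the shares were 59% for genotype and 44.1% for starvation (Fisher's exact test against the genes tested, p = 0.074 and 0.929). In females they were 57.7% and 54.9% (Fisher's exact test, p = 0.0504 and 0.00418), so the high share with starvation came from females. The test with both sexes together, whose criterion was extended after its result was seen, leaves open a chromosome 3 that differs between the stocks. Among all genotype calls in males 63.1% lay there, against 43.7% of the genes tested and 44.2% of the starvation calls, as such a chromosome would give. In females these shares lay closer together, at 47.3%, 44% and 45.7%. The shares cannot set other background apart from the Lipin allele.

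Few X-linked genes were called between the genotypes in males, 3.59% against 15.7% tested. Of the genes called with starvation in WT males 13.3% were X-linked, also below 15.7% (Fisher's exact test, p = 0.000635) but far above 3.59%, which argues against low power for X-linked genes as the whole cause. In females 19.1% of the genotype calls were X-linked, as an X common to males of both genotypes beside other chromosomes that differ would give. The labels do not give the direction of the crosses, so this could not be tested further, and for genes such as HSPBAP1 other background cannot be set apart from the Lipin allele.

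Of 19 genes for carbohydrate-digesting enzymes 11 rose with starvation in WT females and none fell (median log2 1.74), against 3 higher and 5 lower of 20 in males (-0.549). The list had adjusted p = 0.29 with an estimated correlation in females and 0.101 for the difference between the sexes. Loss of ovarian RNA, which could raise the share of all other tissues, was argued against by muscle, neuron and photoreceptor genes, 58 in all, whose upper quartile of change in the same females was 0.214. Depth was argued against by a ratio of mean totals, starved over fed, of 0.991. Fed males already stood above starved females in 17 of 20 of these genes, with a median log2 ratio of 0.832 (quartiles 0.651 and 1.72). No set of other genes was compared in this way. Lpin too was higher in fed WT males (139.2 CPM) than in starved WT females (76.4 CPM). The ratio therefore cannot tell a difference of these enzyme genes from one between whole male and female bodies.

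Dividing the same 6 libraries anew gives 10 splits, too few for a share under 0.05. The real split was the only 1 with as many genes for starvation in WT males (2198, highest other 0), ΔNLS males (2344, 1), WT females (646, 1) and ΔNLS females (906, 1), and for genotype in fed males (178, 0), fed females (275, 7) and starved females (106, 0). For genotype in starved males 2 of 10 splits had as many, with 798 genes against the real 171 where WT libraries 1 and 3 and ΔNLS library 1 were set against the others, which points to a structure of these libraries other than genotype. The size of the starvation response divided the libraries in the same way, with mean log2 changes of 0.839, 0.702 and 0.82 against 1.22, 1.04 and 0.981, and so did Gart, at 501, 223 and 404 against 1020, 1050 and 905 CPM. Why the response differed in size was not tested. With 100 splits, only the real 1 had as many as the 929 of genotype averaged over feeding in females (highest other 3), the smallest share that 100 splits can give. This argues against chance there, and cannot set the Lipin allele apart from other background that goes with the genotype. In males 2 had as many as 502 (highest other 502), and the other of these kept the genotypes of all fed libraries. For sex by feeding 2 had as many as 679 (highest other 1247) and for sex by genotype 2 as many as 770 (highest other 1656). The highest of each kept the true groups almost whole in at least 1 sex, so these splits carry real effects and do not settle chance for an interaction. Every split matches the 0 genes of the genotype by feeding interaction (100 of 100 in males and in females, highest other 502 and 6), so nothing was tested there, and the split with 502 in males kept the genotypes of all fed libraries.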

How the results depend on the processing

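No test in this part was chosen after its result was seen. Counts kept within 1.5 times unless given here, and where they did not, the cause was not tested. With the batch number as a block, genotype in females called 105 genes fed, 46 starved and 531 averaged. The block ended 70 calls among 576 results of named genes (a gene in a comparison, Lpin included where it was not called) and 4 of 137 calls of lists. These are given where the report names them or left out. Other genes were followed with the block only as counts per comparison. DESeq2 called 338, 346 and 762 genes for genotype in fed males, starved males and averaged, and 7 for the male interaction. In females DESeq2 called 1019 and 1789 for starvation in WT and ΔNLS, 1821, 462 and 2055 for genotype fed, starved and averaged, and 20 for the interaction, with 1068 for sex by feeding and 1570 for sex by genotype. All 24 libraries together gave 1632 for starvation in ΔNLS females, 2269, 266 and 2112 for female genotype fed, starved and averaged, and 1 for the female interaction. The 2 groups alone gave 1269 for starvation in WT males, 73 for genotype in starved males, 338 for starvation in WT females and 47 for genotype in fed females, with fewer libraries to estimate the spread. Of 137 list calls 2 held with an estimated correlation and 42 by fry, which called 45 lists in all. RLE scaling, limma-voom and both filters moved no count by over 1.5 times. Leaving out 1 library gave 1264 to 2497 genes for starvation in WT males, 1354 to 2288 in ΔNLS males, 314 to 578 in WT females and 379 to 578 in ΔNLS females. It gave 73 to 148 for genotype in fed males, 85 to 267 in starved males, 337 to 742 averaged, 79 to 212 in fed females, 36 to 93 in starved females and 358 to 1410 averaged. The interaction had 0 to 1 in males and 0 in females, sex by feeding 313 to 1092 and sex by genotype 264 to 1498. No call of a named gene changed direction, but every omission of a library ended some of them. The fewest were 13 of 178 without male ΔNLS starved library 1 and the most 58 of 179 without female ΔNLS starved library 2. Genes in the text were chosen in part for calls that held, so they look steadier than the named genes as a whole. The Lpin change with starvation in ΔNLS females, not called, was 0 on the log2 scale without fed library 3 (adjusted p = 1) and otherwise had adjusted p from 0.331. Depth and 3 libraries per group limit small changes: simulated 1.5-fold changes were recovered in 56.7% of genes in fed males and 31.3% in fed females.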

Other observations

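The gene sets in this part, purine synthesis and cuticle proteins, were chosen only after their values were seen, and no explanation of them was tested.

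Of 10 genes of purine synthesis 7 were higher and 1, Prat2 (-0.88 ± 0.15), lower in starved than fed WT males (median log2 0.758), and 7 higher and none lower in ΔNLS males (1.07). In females 2 were higher in WT, and 1 higher and 1 lower in ΔNLS. No test of the set as a whole, or of its difference between the sexes, was run. Gart, which carries out 3 steps of the pathway, rose in ΔNLS males from 65.1 ± 5.98 to 787 ± 340 CPM (log2 3.60 ± 0.51, adjusted p = 0.000859, n = 3) and AdSL, adenylosuccinate lyase, from 21.0 to 149.8 CPM (2.83 ± 0.27). Single libraries varied widely: Gart stood at 501, 1020 and 223 CPM in starved WT males and 404, 1050 and 905 in starved ΔNLS males, and Pfas at 331, 1290 and 174 and at 313, 991 and 1120 CPM. No gene of the set differed between the genotypes by edgeR (0 of 10 in each comparison).

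Of 56 cuticle protein genes 12 were higher and none lower in starved than fed WT females (median log2 0.66), and 13 higher and 2 lower in ΔNLS females, where 327 of all 10781 genes were higher in WT and 273 in ΔNLS. Several of the 12 stood near the floor or varied widely between libraries. Their means in starved WT females ranged from 0.307 (Cpr76Bb) to 23.6 ± 21.1 CPM (Lcp65Ag3), with Cpr47Eb at 1.09 ± 1.18 CPM. In males 2 of 50 rose and 9 fell in WT, and 6 rose and 10 fell in ΔNLS. Of all 12718 genes tested in males, 552 rose and 1646 fell in WT, and 737 rose and 1607 fell in ΔNLS. Between the genotypes 4 were higher and 1 lower in fed ΔNLS females, none higher and 1 lower in starved ones, and 10 higher and 1 lower averaged over feeding. Of all genes, 218 were higher and 57 lower in fed ΔNLS females, 60 and 46 in starved ones, and 624 and 305 averaged. In ΔNLS males 1 cuticle gene was higher and 2 lower when fed, 2 and 2 when starved, and 4 and 2 averaged. The lower gene in each female comparison was Lcp1, also lower in fed (-4.65) and starved (-4.23) ΔNLS males. This set was not tested as a whole either.

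AttA stood at 39.7, 30.5 and 3.07 CPM in the starved WT male libraries. The first 2 principal components held 52.5% and 18.0% of the variance in males and 45.4% and 21.8% in females, and WT fed female library 1 was highest on the second at 44.5.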
